A study of Mus musculus with 6 samples.

How the data were processed

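RNA-seq count tables of 6 libraries were analysed, from cells labelled as primary mouse aortic smooth muscle cells. Of the libraries, 3 carried a non-targeting hairpin and 3 a hairpin against H3f3b. Per the labels' protocols, 1 microgram of total RNA went into each library and the libraries were made with a KAPA kit that enriches mRNA. The deposited values are raw counts, whole numbers per gene symbol with no scaling. The submitters' processing notes name STAR, featureCounts, DESeq2 and the mouse genome build mm10, and per the file headers each gene carries its exons, strand and summed exon length. Tool versions, whether reads were counted by strand and how reads with several matches were treated are not given in the sources used here. Antisense or overlapping genes and near-identical copies can therefore share or lose counts. Overlap with other annotated genes is given beside 6 named genes; among the other genes that the report names by rule it reached at most 15.9% of exonic sequence, for Dek. Of 55492 gene symbols, 52313 have the same symbol, chromosome, start and end in the GENCODE M21 annotation of the same build, including H3f3b and H3f3a.

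Groups were taken from the sample labels. No sample was left out. Total counts per library were 16577218, 15413259 and 17986533 in shNT and 17448869, 17551719 and 16150907 in shH3f3b, at which 3 counts correspond to 0.167 to 0.195 CPM. The gene with the most counts, CT010467.1, took 2.31% to 2.94% of a library and mitochondrially encoded genes took 1.58% to 1.74% in shNT and 1.28% to 1.39% in shH3f3b. Pearson's r of log2 CPM across genes was 0.994 to 0.996 within groups and 0.964 to 0.970 between groups, where genes are not independent replicates. Within groups, the chi-square per degree of freedom between the counts of any pair of libraries was 1.74 to 5.18, so no pair differed by as little as sampling noise. The percent biological coefficient of variation estimated by edgeR was 4.42.

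The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with robust estimation, TMM scaling, the default filterByExpr filter (minimum count 10) and group as the only term. It was two-sided, and p-values were adjusted by Benjamini-Hochberg over the 13261 genes kept, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01 and adjusted over 28 lists. These lists were contractile and modulated smooth muscle genes, collagens, elastic fibre genes, matrix proteases, cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation, complement, mitosis, DNA replication, H3.3 genes and histone chaperones, p53 targets, cell cycle inhibitors, the TGF-beta pathway, YAP and SRF targets, immediate early genes, osteochondrogenic genes, stress responses, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, and markers of macrophages, endothelium, adventitial fibroblasts and adipocytes. Camera compares a list with the other genes. None of its 10 calls holds when the correlation is estimated from these 6 libraries. That version also takes its degrees of freedom from the 6 libraries and not from the genes, which lowers its power. The cytokine list lost its call with an estimated correlation of -0.0057, under the preset 0.01. A lost call there does not by itself tie the result to correlation between genes.

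The groups, tests, lists and the rule for named genes were set before the data were examined. The rule takes H3f3b and H3f3a; the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of at least 3, separated groups and an established symbol; up to 4 members of each list with the smallest adjusted p; and Acta2, Myh11, Tagln, Cnn1, Ccl2 and Il6 whatever their values. Cdh5, Kdr, mt-Rnr1 and mt-Rnr2 fall outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

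The alternatives were median-of-ratios and upper-quartile scaling, no filter and a stricter filter (5 CPM in 3 samples), the replicate number as a term, each library left out in turn, DESeq2 1.42.0, limma-voom, a stricter threshold of 0.01, edgeR's glmTreat against a log2 fold change of 1, camera with an estimated correlation and camera on voom values. Chosen after seeing the data were fry, a repeat without shNT replicate 3 and shH3f3b replicate 3, and a repeat on genes whose annotated 3' UTR lacks the 6-mer AGAGTC. For the latter, the longest 3' UTR of each protein-coding gene was taken from GENCODE M21, and every 7-mer was scored by the fold change ranks of its carriers after regression on 3' UTR length and GC content (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Scores were centred on their median and scaled by their median absolute deviation.

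The tests were checked on simulated counts for this comparison, 5 draws from the means, dispersions and library sizes of these genes with 200 genes changed. Of 100 genes changed by log2 0.5, edgeR found 71.8% on average, and of 100 changed by log2 1 it found 91.0%. With dispersions as estimated per gene 9.45% of its calls were false, above the nominal rate, and with dispersions set to the trend 5.02% were; 4.92% and 4.90% of unchanged genes had an unadjusted p under 0.05. On the same draws DESeq2 found 67.0% and 84.8% with 5.36% of calls false, and limma-voom found 71.2% and 91.0% with 8.57% false. The 200 changed genes were split evenly between rises and falls, while the real comparison called 8299 genes. These rates may therefore differ in the real data. Camera found a list shifted by log2 -0.5 in simulated counts and called 0 of the other lists. Genes were drawn independently there, while the estimated correlation in the real libraries was 0.86 for mitotic genes. This check therefore does not test the preset correlation. The 7-mer scan, run on 1 permutation of the fold changes of 11759 genes, gave a lowest score of -4.59. It ranked a 7-mer first in 10 of 10 draws when its 102 to 149 carriers were lowered by 0.3 on the log2 scale. With 901 to 997 carriers it did so in 10 of 10 draws.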

Results

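Cells labelled as primary vascular smooth muscle cells from mouse aorta were profiled by RNA-seq after delivery of a short hairpin RNA. One group of 3 libraries carried a non-targeting hairpin (shNT) and one group of 3 carried a hairpin against H3f3b (shH3f3b). H3f3b is one of the genes that encode the replacement histone H3.3, which is placed into chromatin outside DNA replication. The series places this comparison in work on aortic dissection, the change of smooth muscle cell phenotype and vascular inflammation. Total counts ran from 15413259 to 17986533 per library, and 20253 to 22228 gene symbols had at least 1 count. The labels do not say that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Fold changes are given for shH3f3b over shNT, with n = 3 in each group, and expression levels are CPM, counts scaled to the TMM-adjusted size of each library.

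H3f3b RNA was lower in every shH3f3b library than in every shNT library. Its level was 383 ± 15.2 CPM (SD, n = 3) in shNT and 208 ± 9.20 CPM (SD, n = 3) in shH3f3b, a log2 fold change of -0.88 (SE 0.04), which left 54.3% of the shNT level. The shNT libraries held 399, 381 and 369 CPM of H3f3b, and the shH3f3b libraries held 215, 198 and 212 CPM. H3f3a, the sister gene that encodes the same protein, also fell, from 42.0 ± 1.97 to 34.0 ± 2.94 CPM (SD, n = 3), a log2 fold change of -0.30 (SE 0.07, edgeR adjusted p = 0.00043). H3f3b gave 90.1% of the summed H3f3a and H3f3b CPM in shNT and 86.0% in shH3f3b, and that sum fell to 57.0% of its shNT level. In the mm10 coordinates of the count tables H3f3b lies on the minus strand of chr11 from 116021912 to 116027962 and H3f3a on the minus strand of chr1 from 180800832 to 180813943. Both genes have processed copies elsewhere in the genome, and how reads that match several places were counted is not given in the sources used here, so reads shared among them are a source of uncertainty in both values.

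**Figure D1:**
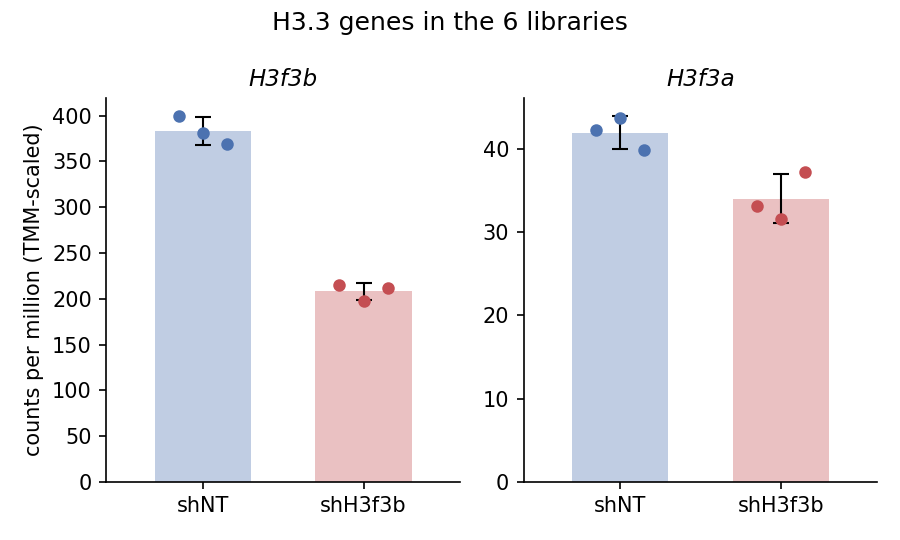
CPM of H3f3b and H3f3a in each library (points), with the group mean (bar) and SD (error bar, n = 3), on axes that start at 0. H3f3b stood at 369 to 399 CPM in shNT and 198 to 215 CPM in shH3f3b.

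Knockdown of H3f3b went with lower RNA for the machinery of DNA replication and mitosis, for cholesterol synthesis, for several chemokines and for most endothelial markers. Of the YAP and SRF targets 14 of 19 rose, and of the p53 targets 15 of 24. None of the list calls behind these groups holds with an estimated correlation (adjusted p = 0.53 for each), and that of the p53 targets ends under a stricter filter on low counts (adjusted p = 0.051) and among genes whose annotated 3' UTR lacks the 6-mer AGAGTC (adjusted p = 0.10). The contractile smooth muscle genes moved both ways: Acta2, Myl9, Cnn1 and Tagln rose while Mylk and Csrp1 fell. Csf1, which encodes a macrophage growth factor, rose from 2603 ± 131 to 7425 ± 227 CPM (SD, n = 3), a log2 fold change of 1.51 (SE 0.04), while the chemokine gene Cxcl1 fell from 16.4 ± 0.573 to 2.78 ± 0.220 CPM (SD, n = 3), a log2 fold change of -2.56 (SE 0.12). Across the transcriptome, 8299 of 13261 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4102 of them higher and 4197 lower in shH3f3b. This balance is relative. TMM scaling sets the fold changes around 0 (median -0.011 over tested genes), and a change in total RNA would not show. Most of the called changes were small, with a median absolute log2 fold change of 0.47. Among the 1297 called genes that differed by at least 1 log2 unit, 958 were lower and 339 higher, so that 73.9% were lower. In 8877 tested genes (66.9%) the libraries of the groups did not overlap, where chance gives 10%. The first principal component took 81.0% of the variance and separated the groups.

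Tppp, which encodes a tubulin polymerization promoting protein, had the largest rise among the well-expressed named genes, from 2.66 ± 0.204 to 31.7 ± 6.95 CPM (SD, n = 3), a log2 fold change of 3.57 (SE 0.20). It was followed by the neuropeptide precursor gene Vgf at 2.22 (SE 0.10), the small proteoglycan gene Ogn at 2.16 (SE 0.23), the collagen-binding integrin gene Itga11 at 2.10 (SE 0.07) and Agap2 at 2.05 (SE 0.12). Olfml2b, Neb, Garem2, Pfn2, Plcxd2, the mechanosensitive channel gene Piezo2 and the protease inhibitor gene Serpinb1a rose by log2 1.79 to 1.89. The largest fall was that of the keratin gene Krt19, from 39.5 ± 3.09 to 3.33 ± 0.655 CPM (SD, n = 3), a log2 fold change of -3.56 (SE 0.11). It was followed by Asf1b, a chaperone of histones H3 and H4, at -2.73 (SE 0.15), by Ces1g at -2.65 (SE 0.18), by Cxcl1, and by the thioredoxin gene Txn1 at -2.56 (SE 0.07). Sprr1a, the galectin gene Lgals3, the pyrophosphate-producing enzyme gene Enpp1, Tlcd2, Pimreg, the osteopontin gene Spp1 and Aldh3a1 fell by log2 values between -2.54 and -2.27. The annotated 3' UTRs of Asf1b, Ces1g, Txn1 and Enpp1, and among the risers those of Tppp and Plcxd2, hold GAGAGTC or AGAGTCA, a pair of overlapping 7-mers that also occur in the H3f3b coding sequence. Ces1g and Serpinb1a belong to families of similar neighbouring genes, and 18.8% of Spp1, 10.6% of Tlcd2 and 8.23% of Garem2 exonic sequence is shared with another annotated gene, so part of their counts may belong to those.

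**Figure D2:**
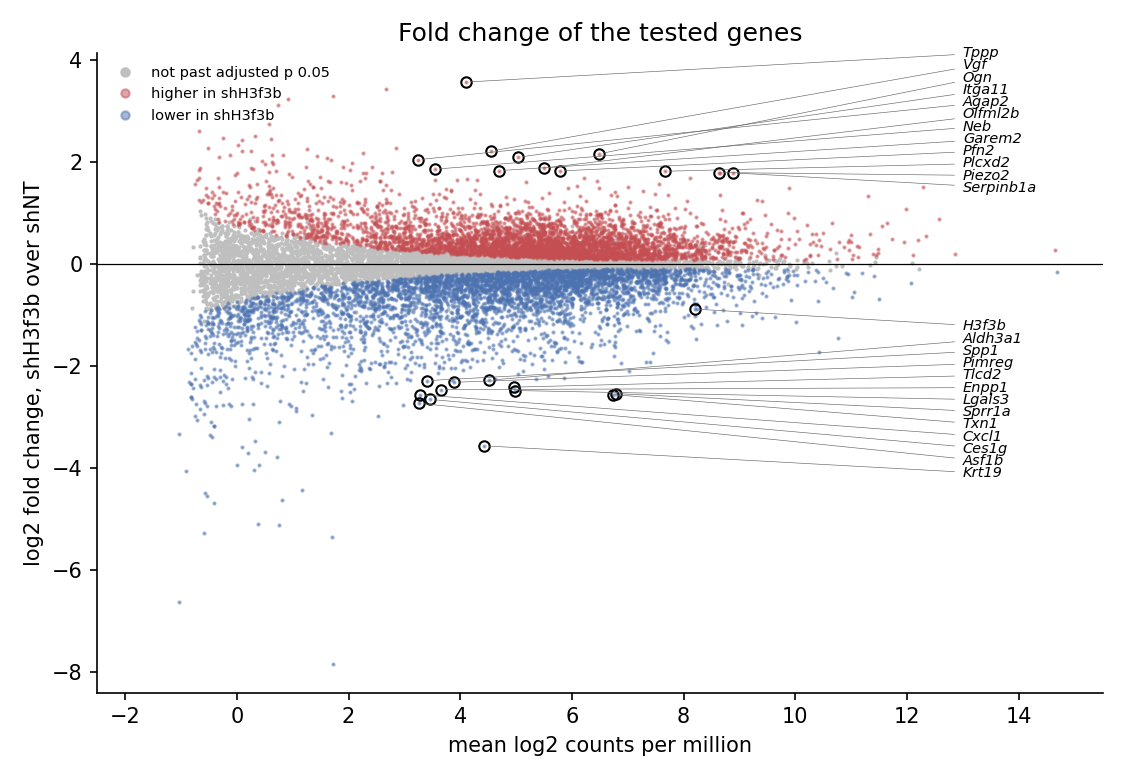
Log2 fold change of shH3f3b over shNT (vertical axis) against mean log2 CPM (horizontal axis) for the 13261 tested genes, with red for genes higher and blue for genes lower at an adjusted p of 0.05 and grey for the rest. Circles mark H3f3b and the 12 named genes with the largest change in each direction, from Tppp at 3.57 to Krt19 at -3.56; points farther from 0 than these lie at a mean log2 CPM under 3.

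Genes of DNA replication fell almost without exception. Of 27 measured members of the list, 25 fell, 0 rose and 2 did not pass, with the same counts when adjusted over the list alone (median log2 fold change -1.41, camera adjusted p = 1.2e-09; adjusted p = 0.53 with an estimated correlation). The helicase subunit genes Mcm4 and Mcm7 fell by log2 -2.24 (SE 0.08) and -1.39 (SE 0.06), the sliding clamp gene Pcna by -1.37 (SE 0.06) and Uhrf1, which encodes a factor that maintains DNA methylation, by -1.89 (SE 0.08). All 24 measured mitotic genes fell, also when adjusted over the list alone (median -1.43, camera adjusted p = 6.5e-09; adjusted p = 0.53 with an estimated correlation). Among them were the spindle midzone gene Prc1 at -2.06 (SE 0.07), the cyclin gene Ccna2 at -1.94 (SE 0.08) and the centromere genes Cenpf at -1.66 (SE 0.09) and Cenpa at -1.28 (SE 0.09). Of 17 H3.3 genes and histone chaperones, 12 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0092; adjusted p = 0.53 with an estimated correlation). Besides Asf1b, the H3-H4 chaperone gene Nasp fell by -1.48 (SE 0.06), Dek fell by -1.12 (SE 0.05) and the centromeric histone chaperone gene Hjurp fell from 96.0 ± 2.88 to 48.0 ± 2.15 CPM (SD, n = 3). This list overlaps DNA replication in function, since Asf1b and Nasp serve histone deposition at replication forks, and Mcm2 stands in both lists. It also holds H3f3a and the targeted gene H3f3b, whose fall the hairpin was meant to cause, and both are among the 12 that fell. Prc1 and Mcm4 hold one of the 7-mers named above.

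p53 targets leaned upward: 15 of 24 rose and 6 fell, also when adjusted over the list alone (median log2 fold change 0.32, camera adjusted p = 0.025). The adjusted p was 0.53 with an estimated correlation, 0.051 under a stricter filter on low counts and 0.10 among genes without the 6-mer AGAGTC in their annotated 3' UTR, so the call ends in each of these. The 18 members without the 6-mer had a median of 0.30, with 11 higher and 4 lower. Ccng1 rose by 0.66 (SE 0.04), Sesn2 by 0.77 (SE 0.05) and the death receptor gene Fas by 0.76 (SE 0.05), while Ckap2, a spindle gene, fell by -1.72 (SE 0.08). Among 16 cell cycle inhibitors and senescence-related genes 9 rose and 4 fell, also when adjusted over the list alone, and the list did not pass as a whole (camera adjusted p = 0.37). The inhibitor genes Cdkn2b, Cdkn1b and Cdkn1a rose by 1.22 (SE 0.06), 0.46 (SE 0.04) and 0.44 (SE 0.04), and the nuclear lamina gene Lmnb1 fell by -1.16 (SE 0.06). Sesn2 and Cdkn1b, both higher, hold one of the 7-mers named above.

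The contractile list did not pass as a whole (camera adjusted p = 0.28): of 19 measured members 8 rose and 6 fell, also when adjusted over the list alone. Acta2, the smooth muscle actin gene, rose from 403 ± 5.83 to 720 ± 27.1 CPM (SD, n = 3), a log2 fold change of 0.84 (SE 0.04). The myosin light chain gene Myl9 rose by 0.96 (SE 0.04), the calponin gene Cnn1 by 0.92 (SE 0.11) and Tagln by 0.50 (SE 0.04), although 67.9% of Tagln exonic sequence is shared with Pcsk7 and another gene. The myosin light chain kinase gene Mylk fell by -1.04 (SE 0.05) and Csrp1 by -0.72 (SE 0.05). Myh11, the myosin heavy chain gene that marks mature smooth muscle, was low in both groups, at 1.04 ± 0.0977 CPM in shNT and 1.46 ± 0.0675 CPM in shH3f3b (SD, n = 3; log2 fold change 0.49, edgeR adjusted p = 0.10). Of 18 genes of the modulated, or synthetic, smooth muscle state 9 fell and 4 rose (4 rose and 10 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.26). Among genes without the 6-mer AGAGTC in their annotated 3' UTR it did pass, downward (camera adjusted p = 0.0082), in a repeat chosen after seeing the data. The adjusted p was 0.53 with an estimated correlation over all tested genes, and that correlation was not estimated in the repeat. Lgals3 fell by -2.48 (SE 0.07), Spp1 by -2.28 (SE 0.13) and the transcription factor gene Klf4 by -0.64 (SE 0.04). S100a4 also fell, by -0.76 (SE 0.06), with 51.7% of its exonic sequence shared with a predicted gene.

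YAP and SRF targets, genes that respond to actin tension, leaned upward: 14 of 19 rose and 3 fell, also when adjusted over the list alone (median 0.28, camera adjusted p = 0.0069; adjusted p = 0.53 with an estimated correlation). The cytoplasmic actin genes Actg1 and Actb rose by 0.79 (SE 0.04) and 0.55 (SE 0.04), the growth factor gene Tgfb2 by 0.72 (SE 0.04) and Ptpn14 by 0.72 (SE 0.05). The collagens were split, with 9 of 19 higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.67). Col14a1 rose by 1.01 (SE 0.04) and the basement membrane gene Col4a2 by 0.81 (SE 0.04), while Col1a1 and Col12a1 fell by -1.11 (SE 0.05) and -1.11 (SE 0.06). Elastic fibre genes were split likewise, with 9 of 19 higher and 8 lower, also when adjusted over the list alone (camera adjusted p = 0.87); their median was 0.18, their mean -0.01. Efemp1 fell by -1.03 (SE 0.05) and Loxl4 by -0.97 (SE 0.06), and Ltbp1 rose by 0.72 (SE 0.04). Among 21 matrix proteases and their inhibitors 6 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.95, with a median of 0.05 and a mean of -0.11). The aggrecanase gene Adamts4 fell by -2.03 (SE 0.10), the plasminogen activator gene Plat fell by -0.57 (SE 0.05) and the gelatinase gene Mmp2 rose by 0.43 (SE 0.04). Of 22 TGF-beta pathway genes 7 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.87). The ligand gene Tgfb3 fell by -1.90 (SE 0.10) and the receptor gene Acvrl1 by -1.03 (SE 0.04), while the receptor gene Tgfbr2 rose by 0.58 (SE 0.04). Csrp1, Efemp1, Col12a1 and Acvrl1 hold one of the 7-mers named above.

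Genes of chemokines, cytokines and NF-kB targets fell on balance. Of 22 measured members 15 fell and 3 rose (3 rose and 17 fell adjusted over the list alone; median log2 fold change -0.32, camera adjusted p = 0.0075; adjusted p = 0.53 with an estimated correlation). Ccl2, which encodes a monocyte attractant, fell from 441 ± 40.3 to 195 ± 11.8 CPM (SD, n = 3), a log2 fold change of -1.18 (SE 0.07). The adhesion molecule gene Icam1 fell by -0.77 (SE 0.05) and the cytokine gene Lif by -1.04 (SE 0.09), both with a 7-mer named above. Il6 went the other way with Csf1, from 9.37 ± 0.802 to 17.2 ± 1.48 CPM (SD, n = 3), a rise of 0.88 (SE 0.10). Of 30 interferon-stimulated genes 14 fell and 1 rose (1 rose and 12 fell adjusted over the list alone; median -0.40, camera adjusted p = 0.0069). The adjusted p was 0.91 with an estimated correlation, and 0.082 with fry, a test of whether the members move one way on balance. A pair of libraries stood apart on this list: shNT replicate 3 exceeded the mean of the other shNT libraries in 29 of 30 members, and shH3f3b replicate 3 lay below the mean of the other shH3f3b libraries in 30 of 30, by a median log2 difference of -0.57. Without both libraries, a repeat chosen after seeing the data, the list was not called (camera adjusted p = 0.057), with a median of -0.21 and 17 of 31 members lower and 5 higher. Without shH3f3b replicate 3 alone the median was -0.24, with 17 lower and 3 higher (camera adjusted p = 0.016). The chemokine gene Cxcl10 fell by -1.83 (SE 0.14), Zbp1 by -1.61 (SE 0.23), Rsad2 by -1.60 (SE 0.15) and Irf9 by -0.46 (SE 0.06). Antigen presentation genes (1 of 13 rose and 3 fell; 1 rose and 1 fell adjusted over the list alone) and complement genes (2 of 11 rose and 4 fell, also adjusted over the list alone) did not pass, with camera adjusted p = 0.67 and 0.52. The same pair stood apart in all 13 antigen presentation genes, and without both 5 rose and 2 fell. Tapbp fell by -0.86 (SE 0.13), with 29.0% of its exonic sequence shared with other genes, and the complement brake Cd55 fell by -0.86 (SE 0.05).

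Cholesterol synthesis genes fell: 16 of 20 were lower and 2 higher, also when adjusted over the list alone (median -0.56, camera adjusted p = 0.00098; adjusted p = 0.53 with an estimated correlation). Hmgcs1 fell by -0.92 (SE 0.04) and Insig1 by -0.88 (SE 0.05). Genes of the unfolded protein and integrated stress responses fell in 17 of 24 cases and rose in 4, also when adjusted over the list alone (median -0.25, camera adjusted p = 0.0069; adjusted p = 0.53 with an estimated correlation). The transcription factor gene Xbp1 fell by -1.15 (SE 0.05), Edem1 by -1.08 (SE 0.04) and Dnajb11 by -0.81 (SE 0.04), and Xbp1 holds the 8-mer GAGAGTCA in its annotated 3' UTR. Immediate early genes were split (7 of 20 rose and 12 fell, also adjusted over the list alone; camera adjusted p = 0.55), with Klf2 higher by 1.31 (SE 0.10) and Ier3 lower by -0.55 (SE 0.05). Hypoxia and glycolysis genes were split as well (9 of 24 rose and 11 fell, also adjusted over the list alone; camera adjusted p = 0.87), with the vasodilator peptide gene Adm higher by 1.35 (SE 0.08) and Eno1 lower by -0.58 (SE 0.04). Of 23 oxidative phosphorylation genes 6 rose and 4 fell, also when adjusted over the list alone; their median of -0.02 and mean of -0.03 lay on the other side of 0 from the direction of the test (camera adjusted p = 0.87). Ndufa9, a complex I subunit gene with a 7-mer named above, fell by -1.44 (SE 0.06). Of 25 cytosolic ribosomal protein genes 5 rose and 4 fell (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.87), and these genes have many processed copies that can share reads. Of 13 listed mitochondrially encoded genes 8 passed the low-count filter, and mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l did not. Of the 8, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.47), with mt-Nd1 lower by -0.35 (SE 0.04). Since mt-Co1 stood at 4879 CPM in shNT, reads of the untested genes may have been lost in counting, which was not tested. Of the mitochondrial ribosomal RNAs, chosen after their values were seen, mt-Rnr2 fell from 2535 ± 254 to 931 ± 45.8 CPM (SD, n = 3), a log2 fold change of -1.45 (SE 0.07), while mt-Rnr1 did not pass, with a log2 fold change of 0.07 (SE 0.04, edgeR adjusted p = 0.19). All mitochondrially encoded genes together, these included, took 1.72%, 1.74% and 1.58% of counts in the shNT libraries and 1.35%, 1.28% and 1.39% in the shH3f3b libraries. Any reads lost in counting are missing from these shares.

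**Figure D3:**
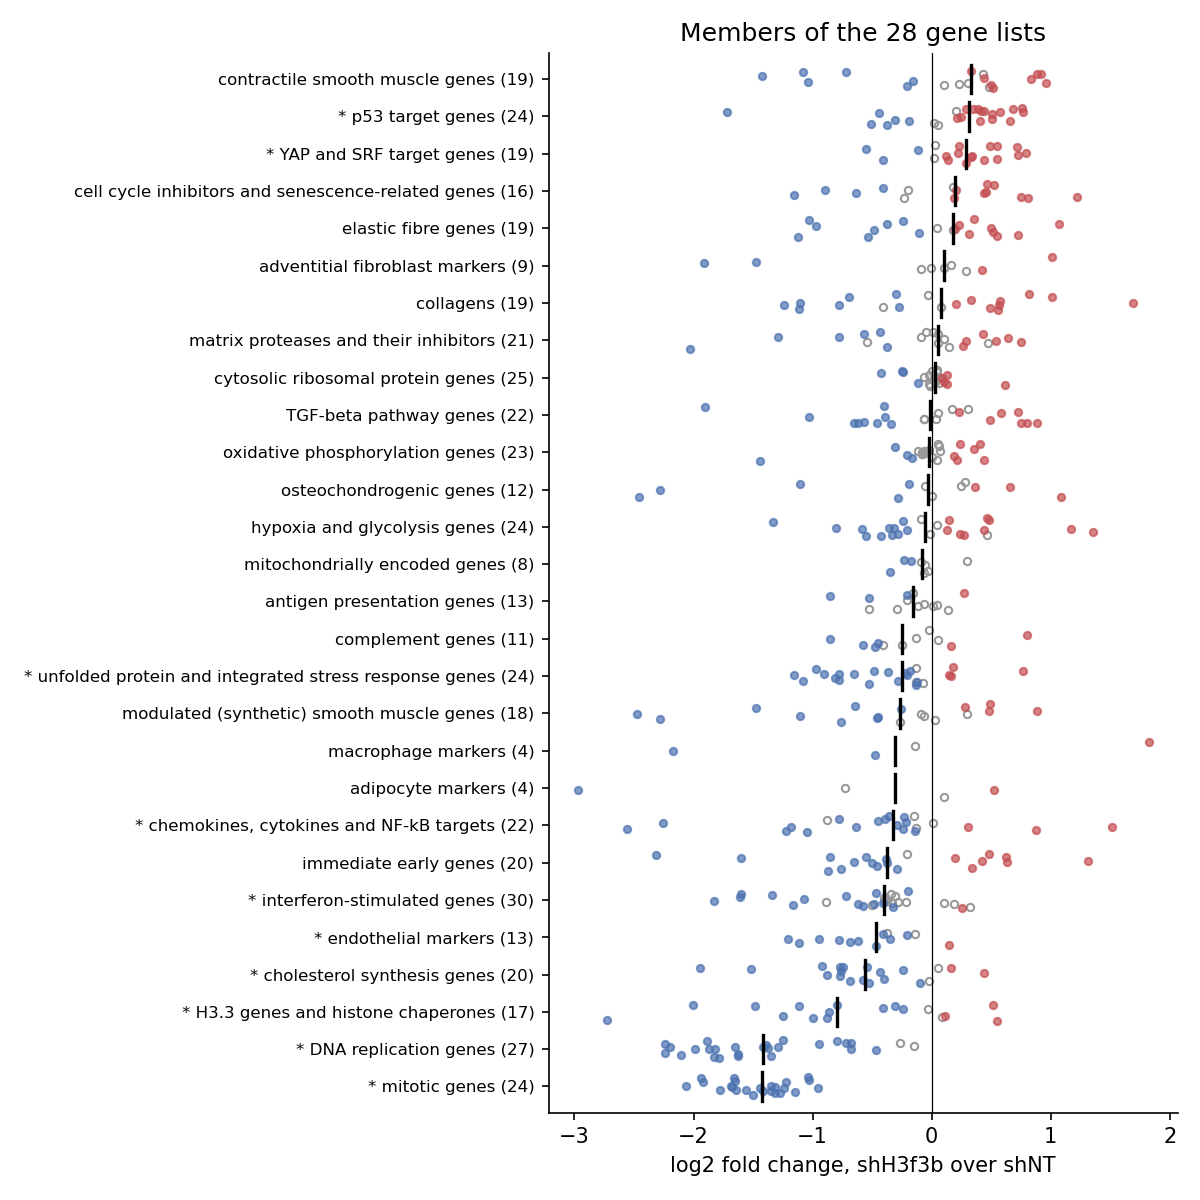
Log2 fold change of shH3f3b over shNT (horizontal axis) for each tested member of the 28 gene lists (rows, number of tested members in brackets), with red for members that rose, blue for members that fell, open circles for the rest and a bar at the list median. An asterisk marks the 10 lists past a camera adjusted p of 0.05 with the preset correlation; the lowest medians are those of mitotic genes (-1.43) and DNA replication genes (-1.41).

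Most endothelial markers fell: 10 of 13 fell and 1 rose, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.0069; adjusted p = 0.53 with an estimated correlation). Emcn, which encodes an endothelial sialoglycoprotein, stood at 1199 ± 19.5 CPM in shNT and 904 ± 23.2 CPM in shH3f3b (SD, n = 3), a log2 fold change of -0.41 (SE 0.04). The junction gene Pecam1 fell from 484 ± 27.98 to 283 ± 6.19 CPM (SD, n = 3), a log2 fold change of -0.78 (SE 0.04), and Tie1 fell by -0.62 (SE 0.04). Not all markers were abundant: Kdr, which did not pass, stood at 2.77 ± 0.957 CPM in shNT and 2.49 ± 0.397 CPM in shH3f3b (SD, n = 3). The 1 member that rose was the endothelial cadherin gene Cdh5, at 556 ± 12.5 CPM in shNT and 614 ± 17.97 CPM in shH3f3b (SD, n = 3), a log2 fold change of 0.14 (SE 0.04). Pecam1 and Emcn hold one of the 7-mers named above, and Tie1 and Cdh5 do not. Markers of macrophages, with 4 of 18 tested, included Cd68, which fell by -2.18 (SE 0.23) from 5.80 ± 0.467 to 1.27 ± 0.669 CPM (SD, n = 3), and Lyz2, which rose by 1.82 (SE 0.27) from 0.658 ± 0.190 to 2.39 ± 0.429 CPM (SD, n = 3). On the macrophage list 1 gene rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.83). Of 9 adventitial fibroblast markers 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.87, with a median of 0.10 and a mean of -0.17), with Gsn higher by 0.42 (SE 0.04) and Ly6c1, one of a family of similar genes, lower by -1.91 (SE 0.16). Of 4 adipocyte markers 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.87); Plin4, with the 8-mer GAGAGTCA in its annotated 3' UTR, fell by -2.97 (SE 0.20). Of 12 osteochondrogenic genes 3 rose and 5 fell (4 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.87). The cartilage collagen gene Col2a1 rose from 2587 ± 76.3 to 5476 ± 120 CPM (SD, n = 3), a log2 fold change of 1.08 (SE 0.04).

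**Figure D4:**
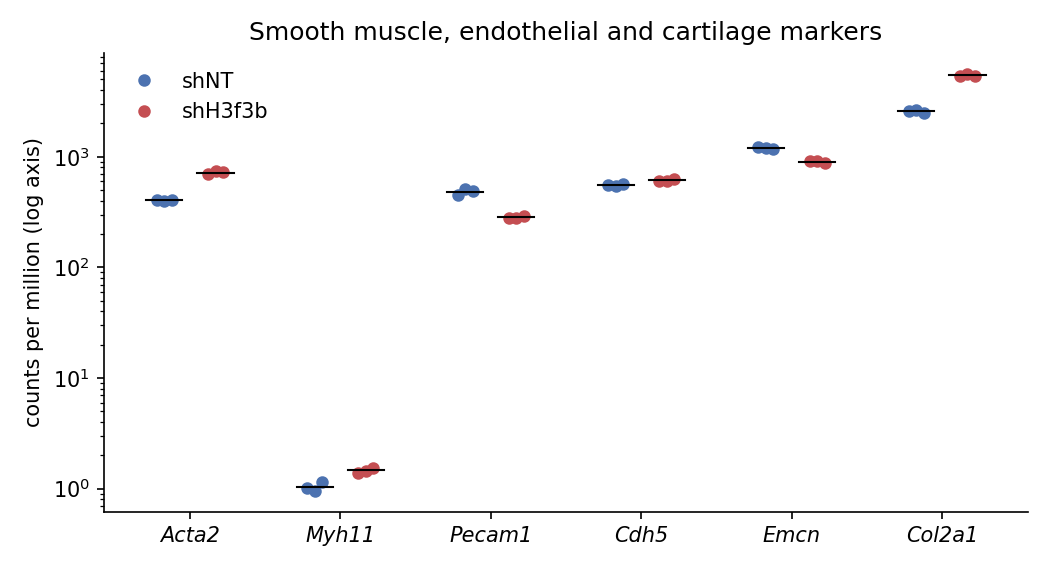
CPM (log axis) of smooth muscle markers (Acta2, Myh11), endothelial markers (Pecam1, Cdh5, Emcn) and a cartilage marker (Col2a1) in each library (points), with group means as lines. Myh11 stood at 1.04 CPM in shNT and 1.46 CPM in shH3f3b, against 484 and 283 CPM for Pecam1 and 2587 and 5476 CPM for Col2a1.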

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

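The tests with fry, those on genes without the 6-mer and those without both shNT replicate 3 and shH3f3b replicate 3 were chosen after the results were seen. The calls of H3f3b and H3f3a kept direction and threshold under the other scalings and filters, the replicate block, DESeq2 and limma-voom. The same held without any 1 library and without both replicates 3. These genes were not read in the repeat without the 6-mer or with glmTreat, where both changes are smaller than the tested size. Without 1 library at a time their log2 fold changes ran from -0.91 to -0.84 and from -0.36 to -0.25. The 8299 called genes became 8308 and 8315 under the other scalings, which also centre the fold changes and so cannot show a change in total RNA. They numbered 8581 without a filter, 7128 with a stricter one, 7007 with DESeq2, 8297 with limma-voom and 7707 to 8044 without 1 library. The 1297 genes past 1 log2 unit became 1822 without a filter, 1379 to 1428 without 1 library, 741 under the stricter filter, which tests fewer genes, and 549 with glmTreat, which tests against that size. Among the 8133 genes whose 3' UTR lacks the 6-mer, 5187 were called, 2301 of them lower, and 657 passed 1 log2 unit, with fewer genes tested. The 10 called lists stayed 10 without any 1 library and became 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05, and 16 with fry, which does not compare a list with other genes. The p53 list ended at adjusted p = 0.051 under the stricter filter and 0.10 among genes without the 6-mer, where 18 of its 24 members had a median of 0.30 against 0.32 (0.00062 to 0.53 over all alternatives), and the interferon list at 0.082 with fry and 0.057 without both replicates 3 (0.00054 to 0.91), where 7980 genes and 9 lists were called. The modulated smooth muscle list, not called at 0.26, passed at 0.0082 among genes without the 6-mer and 0.00039 with fry.

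Directions of lists that camera did not call turned in places, coded 1 for higher and -1 for lower. Without a filter they became -1 for proteases and 1 for TGF-beta, hypoxia and macrophage genes. With a stricter filter oxidative phosphorylation became -1. Without shH3f3b replicate 1 osteochondrogenic and hypoxia genes became 1, and without shH3f3b replicate 2 elastic fibre genes became -1. With fry elastic fibre, protease (adjusted p = 0.013) and oxidative phosphorylation genes became -1 and osteochondrogenic genes 1. Without the 6-mer collagen, elastic fibre, ribosomal and fibroblast genes became -1 and adipocyte genes 1. Without both replicates 3 antigen presentation and adipocyte genes became 1. Csf1r, not called, ran from -0.29 to 0.020 without 1 library, above 0 without shNT replicate 1. Erap1 was called at -0.20 and not past the threshold without shNT replicate 2, shNT replicate 3 or shH3f3b replicate 3 (-0.22, -0.13 and -0.11) with DESeq2 (-0.19) or without both replicates 3 (-0.05), and mt-Cytb was called at -0.17 and not without shNT replicate 1, shNT replicate 2, shH3f3b replicate 1 or shH3f3b replicate 2 (-0.14, -0.14, -0.16 and -0.13). The cause was not tested.

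The replicate numbers do not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.18 to -0.04, and 0 libraries correlated best with their own number. With the number as a block 7780 genes were called, proteases turned to -1, and Psmb8 and Erap1 did not pass (adjusted p = 0.070 and 0.097). Depth limits genes of low level: the SE of the log2 fold change was 0.25 for Myh11, near 1 CPM, against 0.04 for Acta2.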

Other observations

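The tests on endothelial markers and the repeat on genes without the 6-mer were chosen after the results were seen, as were the genes named in the next paragraph and in the weighing.

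Of the most abundant genes (mean log2 CPM above 9), 15 differed by at least 1 log2 unit, 8 higher and 7 lower in shH3f3b. The D-type cyclin genes Ccnd2 and Ccnd1, whose products drive entry into the cell cycle, fell from 2116 ± 148 to 638 ± 5.24 CPM and from 919 ± 20.2 to 440.1 ± 7.72 CPM (SD, n = 3), log2 fold changes of -1.73 (SE 0.05) and -1.06 (SE 0.04). Fscn1, which encodes an actin-bundling protein, rose from 1425 ± 72.3 to 3626 ± 113 CPM (SD, n = 3), a log2 fold change of 1.35 (SE 0.04), and Dpysl3, Lbh and Ahcyl1 rose by 1.23 (SE 0.04), 1.27 (SE 0.04) and 1.49 (SE 0.08). The receptor genes Pdgfrb and Notch3 rose by 0.55 (SE 0.04) and 0.79 (SE 0.08). Flt1 and Plvap, both typical of endothelium, fell from 196 ± 7.30 to 97.7 ± 5.37 CPM and from 107 ± 2.30 to 30.2 ± 3.71 CPM (SD, n = 3), and the intermediate filament gene Nes fell by -1.52 (SE 0.05).

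Many genes of unrelated function fell in shH3f3b, and the short hairpin itself may account for part of this through matches of its seed in 3' UTRs, as a microRNA would. Among 16369 7-mers, GAGAGTC had the lowest score, at -14.39 against a lowest of -4.59 in 1 permutation of the fold changes. The lowest score among 417 other 7-mers of the same base composition was -7.72. Of the 17 7-mers below -6, 15 hold GAGTC. GAGAGTC lies in the H3f3b coding sequence, at chr11 from 116023464 to 116023470 (mm10) in exon 4 of H3f3b-201, followed by A. The share of all 7-mers that this mRNA holds was not counted, so the weight of its presence there is not known. Median log2 fold changes were -0.34 for the 326 genes with GAGAGTCA, -0.20 for other carriers of GAGAGTC and -0.12 for AGAGTCA. They were -0.03 for the 6-mer AGAGTC and 0.04 for genes with none. Of the genes lower by at least 1 log2 unit 30.1% hold one of the 7-mers, against 13.8% of genes not called and 14.6% of genes higher by at least 1. GAGAGTC was picked from these same fold changes, so these medians and shares describe the pick and do not test it. Unlike the score, they are not adjusted for 3' UTR length or GC content. A change in an endogenous small RNA with the same seed would look alike, and the labels name 1 hairpin without its sequence. Loss of H3.3 stays open as a cause for genes with a site and for genes without one. Of genes with none of the sites 28.3% were called lower and 35.4% higher. Of those with GAGAGTCA 57.7% were called lower and 16.6% higher.

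Seed matches do not directly account for the fall of DNA replication and mitotic genes. The 49 such genes without GAGAGTC had a median log2 fold change of -1.41 (95% bootstrap interval over genes -1.65 to -1.31). The 42 of them that also lack the 6-mer AGAGTC had a median of -1.47 (-1.65 to -1.35). The prediction set beforehand for direct seed action was a median above -0.3, a cut-off that was chosen and not measured. These genes move together, so the intervals do not measure the spread between libraries. An indirect route stays open and was not tested: Ccnd2 carries GAGAGTC in its 3' UTR and Ccnd1 carries none of the sites. Loss of H3.3, the biological explanation that the design names, also stays open.

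A lower share of endothelial cells in the shH3f3b cultures was weighed for the fall of endothelial markers. It would lower the abundant markers alike, but Cdh5 exceeded Pecam1 by 0.92 in log2 fold change (SE 0.06), and Tie1, which like Cdh5 holds none of the sites, fell by -0.62 while Cdh5 rose by 0.14. Cdh5 was the only abundant marker that was higher, and the pair was picked after the values were seen. The other abundant markers were all lower, from -0.95 (SE 0.07) for Egfl7 to -0.21 (SE 0.06) for Erg. These unequal changes argue against a change in share as the whole cause, and a lower share as part of the cause stays open. Seed matches in Pecam1 and Emcn may add to their fall. Whether the markers come from endothelial cells in the cultures, from the labelled smooth muscle cells or from cells of another kind cannot be read from these libraries. The label itself was not tested. In shNT, Acta2 stood at 403 CPM, but Myh11, Myocd and Col1a2 stood at 1.04, 0.779 and 1.04 CPM. The cartilage collagen gene Col2a1 stood at 2587 CPM. The changes in contractile and modulated genes are thus those of cells whose identity rests on the label.

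Across the 10 ways to split the 6 libraries into 3 and 3, the real split is 1 of 10, so no share under 0.05 can be reached. The real split called 8299 genes and the highest of the others 0 (edgeR, adjusted p of 0.05). At an unadjusted p under 0.05 the numbers were 8711 and at most 136. Every other split has libraries of both groups on each side, so the group difference counts there as spread and lowers the calls. The contrast is therefore no measure of chance.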
